A study of Mus musculus with 3 samples.

How the data were processed

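Whole viable cells from 2 mouse mammary tumors and from 1 normal mammary gland were profiled by droplet single-cell RNA sequencing with the 10x Genomics 3′ chemistry, with 1 library for each. The tumors arose from the MMTV-PyMT transgene, a viral oncogene driven in the mammary epithelium. The Cxcr4 cKO tumor came from a mouse with floxed Cxcr4 alleles and Cre recombinase expressed from the lysozyme M locus (Lyz2), which is active in macrophages, monocytes and neutrophils. The control tumor came from a littermate with floxed Cxcr4 alleles and no Cre. Both were taken at 15 weeks of age and matched in size, per the labels' protocols. The normal gland came from a wild-type C57BL/6 mouse of 8 weeks. About 15000 cells were loaded for each library.

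The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) for each gene and cell barcode, without normalization. They were written by Cell Ranger, per the file headers, with version 7.1.0 recorded here from the normal gland only and not compared with the tumors. This followed the authors' alignment to the mm10 mouse genome, per the submitters' processing notes. Those notes also name Seurat, and no Seurat output or cell annotation was used here. The gene annotation, the reads per cell and whether reads in introns were counted are not given in the sources used here. Each matrix was deposited in 2 copies that are identical apart from comment lines, so 1 copy was used. The PyMT transgene was not analysed here.

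The 3 matrices hold 13597 barcodes and 31053 features. The totals were 86442852 UMIs in 4929 barcodes for the cKO tumor, 87404728 UMIs in 4469 barcodes for the control tumor and 62411516 UMIs in 4199 barcodes for the normal gland. Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. Doublets were treated by removing, in each library, the highest Scrublet scores up to 0.8% for every 1000 barcodes, which removed 194 barcodes of the cKO tumor, 160 of the control tumor and 141 of the normal gland. Scrublet's own threshold would have marked 83, 73 and 35. This left 4326, 3902 and 3782 cells, 12010 in all, with median depths of 17128.5, 18782.5 and 8984 UMIs.

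The kept cells of the 3 libraries were clustered together with scanpy 1.11.5 in Python 3.11.15, from log-normalised counts of 2000 variable genes, 40 principal components, 15 neighbors and Leiden clustering at resolution 1.0 (igraph 0.11.9). Clusters were named from 19 marker lists written before the data were examined. A name needed at least 3 markers of the class, each in at least 25% of the cluster's cells. A cluster led by cell-cycle genes (cluster 22) was assigned cell by cell from the same markers. All clusters received a name, so each class means cells with that marker pattern, for example macrophage-like or T cell-like, and differences from the authors' own cell types may come from this rebuilt naming. Cluster 18, named macrophage/monocyte, had 5 macrophage markers and 1 marker of another class among its 10 leading genes when set against the other classes. Set against all other cells, other macrophage clusters included, it had 0 and 1, so the macrophage values were also computed without it.

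UMIs were summed for each class and library and divided by the class total to give CPM with exact Poisson 95% intervals. Shares of cells carry exact Clopper-Pearson 95% binomial intervals, ratios of CPM carry exact conditional Poisson 95% intervals, and ratios of shares carry 95% intervals from the binomial error on the log scale. All of these cover counting error only. Each group is 1 library, so no p-value was computed, and no difference has a replicate check. A count of 0 was given the limit that 3 counts allow, and a fold against 0 was computed from that floor as "at least". Shares of cells with a UMI were also computed after thinning every cell to 2000 UMIs, with shallower cells left out.

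Genes were named by a rule fixed before the data were examined. In each class with at least 100 cells in both libraries, a gene needed at least 50 UMIs over both libraries, at least 50 CPM in the higher library, and in that library at least 0.2 of its highest level in any other class of 50 or more cells, which guards against free RNA. Markers of the class itself, mitochondrial, ribosomal, hemoglobin, immunoglobulin, T cell receptor and sex-linked genes used for sexing, and unnamed gene models were left out. Genes were ranked by the bound of the ratio's interval nearest to 1. The first 8 higher and 8 lower were named in macrophages and monocytes, and the first 4 higher and 4 lower in each other such class. The plan was to stop at about 30 genes, but all such classes were taken, which gave 48 pairs of gene and class for the 2 tumors and 40 for the control tumor and normal gland, with some genes in more than 1 class. Cxcr4, Cxcl12 and Ackr3 are reported in addition, as are members at either end of the gene lists described. Lyz2 was added after its values were seen. Of the named genes, 2 are not reported here.

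A total of 35 gene lists was fixed beforehand. For each list with at least 5 members of at least 20 UMIs in a class, the median log2 ratio of its members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile is a description of these libraries, not a test. Members were counted as higher, lower or between by a fixed size of 1.25-fold in either direction. The intervals and list percentiles were run on data simulated with independent Poisson counts, the model that the intervals assume. This checks the calculation, not how UMIs spread over real cells or how list members move together. For macrophages of the 2 tumors the intervals of 11389 simulated genes held a true ratio of 1 in 95.1% of unchanged genes, and a list moved by 1.25-fold stood above every random list. Over the 4 simulated settings, macrophages and luminal cells in both comparisons, the moved list stood above at least 99.85% of random lists, and 3.0% to 8.0% of unmoved lists fell outside the middle 95%.

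Gene coordinates and intron lengths came from GENCODE annotation on GRCm38, the assembly of mm10, in which 30934 of the 31053 features (99.6%) were found by identifier. Other software was numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9, and edgeR 4.0.16 in R 4.3.3, used for TMM scaling of the class sums only. Alternatives tried were no cell filter (doublets still removed), a stricter cell filter, no doublet removal, a doubled doublet share, other clustering resolutions, clustering each library on its own, naming cell by cell, median-of-ratios and TMM scaling, the mean of per-cell CPM, other UMI minimums, and members above the free RNA guard only. Added after seeing the data were leaving Lyz2 out of the naming, leaving out cluster 18, and limits on intron length.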

Results

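The series holds 3 libraries of dissociated mouse mammary tissue, with 1 library for each group. The Cxcr4 cKO tumor gave 4326 kept cells with 79486077 UMIs, the control tumor 3902 cells with 80690287 UMIs and the normal gland 3782 cells with 58485433 UMIs. The comparison of the 2 tumors asks how loss of the chemokine receptor CXCR4 in myeloid cells relates to the cells and transcripts of the tumor. The comparison of the control tumor with the normal gland describes the tumor against its tissue of origin. Each group is 1 mouse, so every difference below also holds whatever sets 1 mouse or 1 tumor apart from another.

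Cxcr4, the receptor of the stromal chemokine CXCL12 (ENSMUSG00000045382, chromosome 1, 128588199 to 128592293 on the minus strand, mm10), was the gene targeted in the cKO mouse. In macrophages and monocytes it stood at 11.9 CPM (95% interval 9.87 to 14.1, 125 UMIs) in the cKO tumor, at 14.7 CPM (12.96 to 16.7, 251 UMIs) in the control tumor and at 202 CPM (182 to 224, 381 UMIs) in the normal gland. The ratio of cKO to control was 0.805 (0.644 to 1.002). A UMI of Cxcr4 was seen in 14.7% of macrophages of the cKO tumor, 17.0% of the control tumor and 74.2% of the normal gland, with median depths of 15239, 16211 and 12233 UMIs. Fibroblasts, which should lack Cxcr4, gave background shares of 1.05%, 4.22% and 3.01% at median depths of 15061, 22583 and 19021 UMIs. After thinning to 2000 UMIs the macrophage shares were 2.11%, 3.66% and 38.5%, with 22, 41 and 3 shallower cells left out, and the fibroblast shares were 0%, 0% and 0.530%. The labels do not say which part of Cxcr4 is deleted, and these libraries read the 3′ end of transcripts, so these values do not check the deletion.

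Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321 on the minus strand), the locus that carries Cre, told the tumors apart. In macrophages and monocytes it stood at 12.6 CPM (10.6 to 15.0) in the cKO tumor against 2701 CPM (2676 to 2725) in the control tumor, which is 214-fold lower (181 to 256), and at 9713 CPM in the normal gland. The low level lies in the library labelled as carrying Cre. The 2 tumors thus differ in Lyz2 transcripts as well as in the labelled Cxcr4 genotype.

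**Figure D1:**
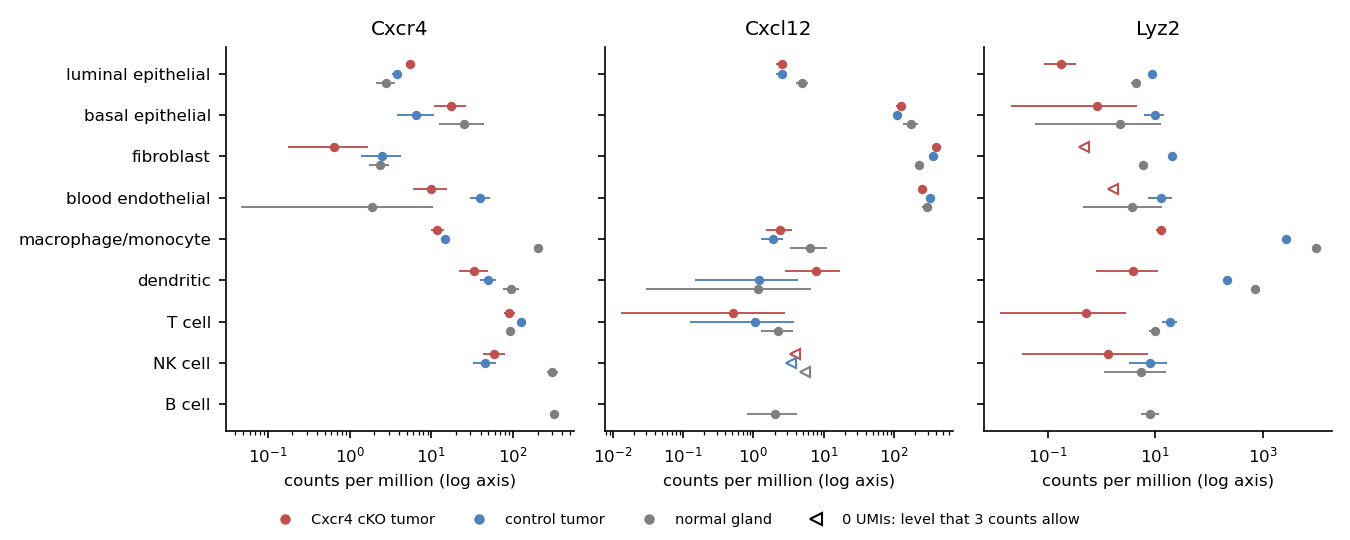
Level of Cxcr4, Cxcl12 and Lyz2 in each cell class (rows) of the 3 libraries (colors), in CPM on a log axis, with exact Poisson 95% intervals as bars and open triangles at the limit for 0 UMIs; classes with few cells in a library are not drawn. In macrophages Lyz2 lies at 12.6 CPM in the cKO tumor and 2701 CPM in the control tumor, while Cxcr4 lies at 11.9 and 14.7 CPM.

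Cxcl12 transcripts were highest in stromal classes in all 3 libraries. Cxcl12 (ENSMUSG00000061353, chromosome 6, 117168535 to 117181367 on the plus strand) stood at 392 CPM (377 to 408) in fibroblasts of the cKO tumor, 363 CPM (348 to 379) in those of the control tumor and 224 CPM (218 to 230) in those of the normal gland. Endothelial cells held 253, 321 and 292 CPM, whereas luminal cells held 2.52, 2.53 and 4.89 CPM and macrophages 2.37, 1.88 and 6.37 CPM. Ackr3 (ENSMUSG00000044337, chromosome 1, 90203980 to 90216751 on the plus strand), a scavenging receptor for CXCL12, was likewise highest in fibroblasts, at 375, 310 and 392 CPM. Among classes with enough cells to measure, Cxcr4 was highest in T cells in the tumors, at 90.3 CPM (77.4 to 105) in the cKO tumor and 126 CPM (111 to 143) in the control tumor, and in the normal gland it was highest in B cells, at 315 CPM (296 to 334), with NK cells at 303 CPM. In endothelial cells Cxcr4 was 3.97-fold lower (2.27 to 7.23) in the cKO tumor, at 9.95 against 39.5 CPM, on 18 UMIs in 12 of 157 cells against 50 UMIs in 13 of 110. A UMI was seen in 7.64% (4.01 to 12.97) and 11.8% of these cells, so a few cells carry the difference.

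In the cKO tumor macrophages and monocytes made up a smaller part of the cells than in the control tumor. They were 15.9% (14.8 to 17.0) of kept cells against 27.0% (25.6 to 28.4), a ratio of 0.589 (0.540 to 0.641), and 61.5% (58.6 to 64.4) of immune cells against 70.3% (67.9 to 72.6). Without cluster 18 the ratio of shares was 0.558 (0.504 to 0.618). Dendritic cells were also a smaller share, 0.902% against 1.999% (ratio 0.451, 0.308 to 0.661), as were basal epithelial cells, 1.502% against 2.56% (0.586, 0.430 to 0.799). T cells were 5.94% and 6.07% of kept cells, a ratio of 0.978 (0.824 to 1.16), and neutrophils were 0.809% and 0.846%. Luminal epithelial cells were a larger share in the cKO tumor, 59.2% against 49.1% (1.21, 1.16 to 1.26), as were fibroblasts, 8.81% against 6.07% (1.45, 1.24 to 1.70), and endothelial cells, 3.63% against 2.82% (1.29, 1.01 to 1.64). Shares of 1 whole move against each other. With each library clustered on its own the macrophage ratio was 0.778, and macrophages were 66.8% of immune cells in the cKO tumor against 63.8% in the control tumor, so the order among immune cells depends on how cells are named. That clustering left 139 control macrophages unnamed and named 47 as B cells, while 39 dendritic cells of the cKO tumor were named macrophages.

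**Figure D2:**
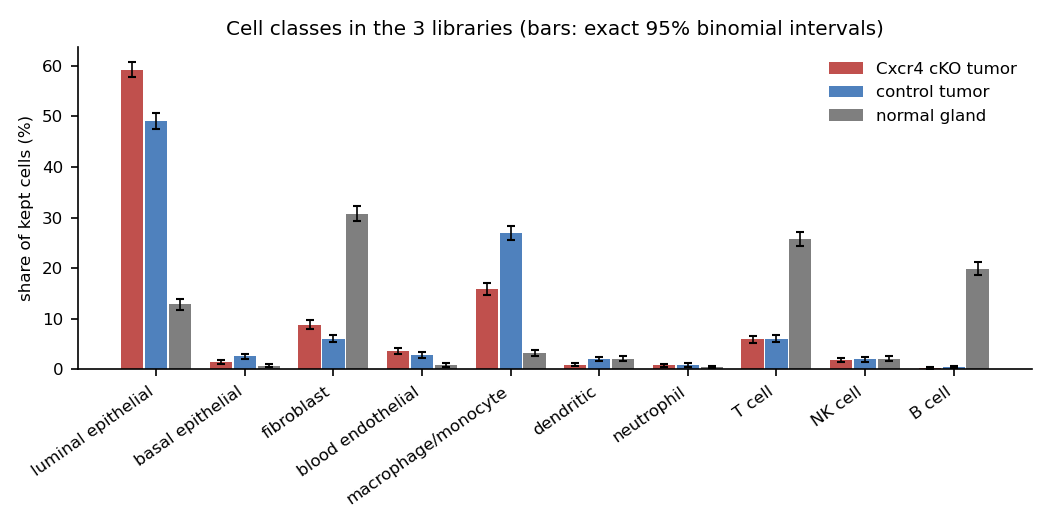
Share of kept cells (percent) in 10 cell classes of the 3 libraries, with exact Clopper-Pearson 95% intervals as bars. Macrophages and monocytes are 15.9% of the cKO tumor, 27.0% of the control tumor and 3.17% of the normal gland.

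Macrophages and monocytes of the cKO tumor (687 cells, against 1053 in the control tumor) had lower levels of several chemokine and cell-cycle transcripts and of Vegfa, and higher levels of Cxcl9 and Hes1. Lower were Ccl7, a monocyte attractant, at 128 against 225 CPM (1.76-fold, 1.65 to 1.87), Thbs1, which encodes the matrix protein thrombospondin 1, at 181 against 316 CPM (1.75-fold, 1.66 to 1.84), Vegfa, the main angiogenic growth factor, at 31.9 against 52.8 CPM (1.66-fold, 1.46 to 1.88), the chemokines Ccl6 (1.60-fold, 1.52 to 1.67) and Ccl9 (1.49-fold, 1.41 to 1.57), and the nuclear receptor Nr4a1 (1.51-fold, 1.41 to 1.63). Cxcl9, an interferon-gamma target that attracts T cells, was higher at 110 against 52.8 CPM (2.08-fold, 1.91 to 2.28), as was Hes1, a transcription factor downstream of Notch, at 137 against 84.6 CPM (1.62-fold, 1.504 to 1.74), and Ptgs1, a cyclooxygenase, at 68.9 against 44.8 CPM (1.54-fold, 1.39 to 1.71). The other genes that the rule named were Mid1, H2-M2, Rttn, Fgf13 and Gclc, 1.504-fold to 1.83-fold higher, and H2-T23 and Ifitm2, 1.74-fold and 1.503-fold lower. Without cluster 18, Hes1 was 1.31-fold higher. The MHC class I gene H2-T23 belongs to a family of near-identical copies and is uncertain.

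Of the 35 gene lists measured in macrophages and monocytes, 11 had medians below and 9 above the middle 95% of random lists. The cell-cycle list was lowest, with a median log2 ratio of −0.41, below every random list, and of its 26 members 16 were counted as lower and 0 as higher, with Ccnb1 2.30-fold and Rrm2 2.25-fold lower. The interferon response list had a median of −0.24, below every random list (9 of 25 members lower, 1 higher), with Ifit1 1.68-fold lower (1.39 to 2.06) and Ifit3 1.57-fold lower, while Cxcl9 went the other way. The inflammatory cytokine list stood at −0.31 (9 of 19 lower, 1 higher), with Ccl7 lower and Il12b, which encodes a subunit of interleukin 12, 1.86-fold higher. The monocyte list stood at −0.19 (7 of 16 lower, 3 higher), the resident macrophage list at −0.23 (3 of 19 lower, 2 higher, with Ccl8 1.36-fold lower and Cd209f 2.54-fold higher), the MHC class I list at −0.20 (3 of 13 lower, 0 higher) and the alternative activation list at −0.17 (3 of 16 lower, 0 higher). The macrophage recruitment list stood at −0.15, the hypoxia and glycolysis list at −0.13 and the list of macrophage growth factors at −0.13. The dissociation stress list, a sign of handling, was lower too, at −0.14 (0.0044 with each library clustered on its own), and the RNA quality list was at −0.02, within 95% of random lists.

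The Notch pathway list in macrophages stood at 0.10, above 97.75% of random lists, with 4 of 20 members higher, 3 lower and 13 between. The median was 0.0054 among the 14 members above the free RNA guard and 0.014 without cluster 18. Its members went both ways, with Hes1 higher and Lfng, a modifier of Notch receptors, 1.32-fold lower. The angiogenic factor list (0.15, 5 of 16 members higher, 3 lower), the MHC class II list (−0.04, 11 of 13 members between), the lipid-associated macrophage list (0.04) and the CXCL12 axis list (0.00) lay within 95% of random lists. In the lipid-associated list Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, was 5.59-fold higher (4.62 to 6.82) at 45.0 against 8.04 CPM, and Spp1 (osteopontin), which luminal cells also express, was 1.91-fold higher. The matrix enzyme list was above random lists at 0.14. The other 7 lists above belong to other cell classes, among them the luminal progenitor list at 0.94 and the collagen list at 0.54, and 0 of the 23 collagen members reached the free RNA guard in macrophages.

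**Figure D3:**
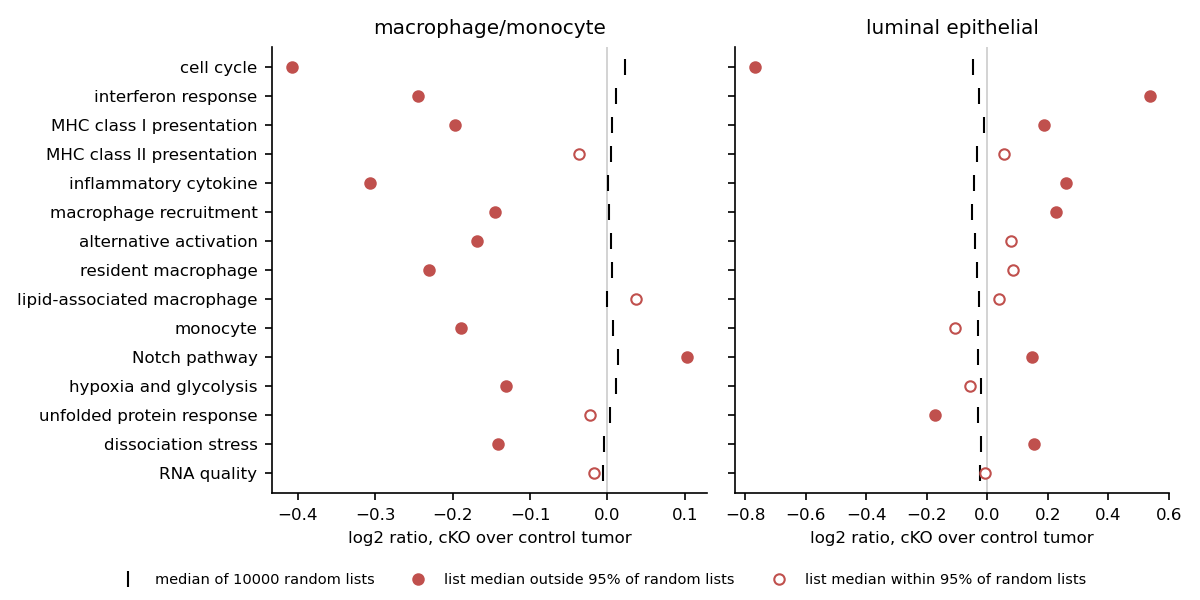
Median log2 ratio (cKO over control tumor) of 15 of the fixed gene lists in macrophages and monocytes and in luminal epithelial cells, as points, filled where the median lies outside 95% of 10000 random lists, with ticks at the median of those lists. The cell-cycle list is lower in both classes (−0.41 and −0.77), and the interferon list is lower in macrophages (−0.24) and higher in luminal cells (0.54).

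Luminal epithelial cells, the largest class of both tumors, differed between the tumors in interferon-response, cell-cycle and hormone-sensing transcripts. Ifi27l2a, an interferon-induced gene, was 3.93-fold higher (3.76 to 4.10) in the cKO tumor at 198 against 50.5 CPM, and Cst3 (cystatin C) was 2.83-fold (2.78 to 2.88), Cck (the hormone cholecystokinin) 2.79-fold (2.65 to 2.93) and Gpc6 (a glypican) 2.504-fold higher (2.44 to 2.56). Sprr1a, a gene of the cornified envelope, was 10.0-fold lower (8.92 to 11.2) at 5.86 against 58.7 CPM, and the acute-phase genes Fgg and Hp were 3.40-fold (3.25 to 3.57) and 3.14-fold lower (2.96 to 3.34), with the cytokine gene Il24 2.69-fold lower (2.55 to 2.83). The interferon response list stood at 0.54, above every random list, with 19 of 25 members higher and 1 lower. The cell-cycle list stood at −0.77, below every random list, with 22 of 26 members lower and 0 higher, for example Rrm2 (2.23-fold, 1.98 to 2.504) and Bub1 (2.004-fold). The hormone-sensing luminal list stood at −0.75, below every random list (10 of 13 lower, 1 higher), with Cxcl15 4.06-fold and Wnt4 2.59-fold lower and Gata3 1.31-fold higher. The clusters within the class differed in share too. Cluster 20, led by Fgb and Fgg, was 2.89% of luminal cells in the cKO tumor and 6.78% in the control tumor, and the cell-cycle cluster 22 was 1.84% and 3.81%. Cluster 19, led by interferon-response genes, was 4.02% and 2.30%, and cluster 4 was 37.3% and 21.1%.

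Among the other luminal lists, the Notch pathway list stood at 0.15 (9 of 23 members higher, 3 lower), with Hey2, a Notch target, 3.48-fold higher. The stem and tumor-initiating list stood at 0.13 (4 of 20 higher, 3 lower), with Aldh1a3 2.04-fold and Itgb3 1.99-fold higher and Lgr5 4.54-fold lower, and the Wnt pathway list at 0.12 although 5 of 23 members were higher and 8 lower. The MHC class I list stood at 0.19 and the unfolded protein response list at −0.17, with Chac1 1.94-fold and Xbp1 1.27-fold lower. The angiogenic factor list stood at 0.17 although Vegfa was 2.16-fold lower, and it turned to −0.18 among members with short introns. The milk list (−0.03) and the hypoxia and glycolysis list (−0.06) lay within 95% of random lists, and in the milk list Glycam1 was 110-fold lower and Btn1a1 1.997-fold higher. The dissociation stress list was higher at 0.15, with Egr1 1.38-fold higher, and RNA quality was at −0.01. The collagen list, foreign to luminal cells, stood at 0.84 with 0 of 23 members above the free RNA guard, and fibroblasts were the larger share in that tumor.

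Fibroblasts of the cKO tumor (381 cells, against 237) had less of the contractile, matrix-depositing transcripts. The myofibroblast list stood at −0.78, below every random list, with 12 of 18 members lower and 0 higher, among them Tnc (tenascin C) at 62.3 against 217 CPM (3.47-fold, 3.10 to 3.91) and Cthrc1 at 18.1 against 68.7 CPM (3.79-fold, 3.06 to 4.72). The collagen and matrix list stood at −0.22 (9 of 23 lower, 0 higher), with Eln (elastin) 2.08-fold lower and Dcn (decorin) 1.22-fold higher. The adventitial fibroblast list stood at 0.58, above every random list (8 of 14 higher, 0 lower), with Efhd1 2.08-fold and Limch1 2.01-fold higher. Cxcl13, a B cell attractant, was 18.4-fold higher (16.0 to 21.3) at 677 against 36.8 CPM, and Mrgprg 12.2-fold, Dmkn 3.46-fold and Lvrn 3.36-fold higher. F5 (coagulation factor V) was 11.0-fold lower (8.55 to 14.4) and Kif26b 4.60-fold lower. Clusters 9 and 5 held most of these cells in both tumors, with cluster 5 at 34.4% of fibroblasts in the cKO tumor and 19.0% in the control tumor. Lists of epithelial cells were higher in these fibroblasts, luminal progenitor at 0.80, hormone-sensing at 0.61, basal keratin at 0.47 and milk at 0.34. Of these, hormone-sensing was −0.079 with no doublets removed, and basal keratin and milk were −0.065 and −0.032 among members with at least 100 UMIs.

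T cells (257 and 237 cells) of the cKO tumor had less of the regulatory T cell transcripts. That list stood at −0.61, below every random list (8 of 11 lower, 2 higher), with Foxp3, which defines regulatory T cells, 3.86-fold lower (2.60 to 5.90) and Tnfrsf4 (OX40) 4.12-fold lower (3.46 to 4.93) at 81.1 against 334 CPM. Cluster 29, led by Frmd5, Tnfrsf4 and Foxp3, was 3.89% of T cells in the cKO tumor (10 cells) and 12.2% in the control tumor (29 cells). The interferon response list in T cells stood at −0.33 (12 of 23 lower, 1 higher) and the cell-cycle list at −0.35 (12 of 21 lower, 1 higher), or −0.015 by the mean of per-cell CPM. Gzma, a cytotoxic granule protease, was 4.33-fold higher (3.72 to 5.06), but 0.799 of the control level when cells were named 1 by 1 from markers. Dach2 likewise went from 4.71-fold higher to a ratio of 0.951. Gzma is itself a marker of NK cells, so that naming can take T cells with Gzma out of the class and does not check Gzma. Pde7b and Tmem87b were 4.39-fold and 4.24-fold higher, but 2.14-fold and 1.73-fold with that naming. Frmd5, Sh3rf1 and Itgb8 were 4.80-fold, 4.03-fold and 4.98-fold lower, and the ratio of Frmd5 was 0.373 by the mean of per-cell CPM and that of Sh3rf1 0.419 with no doublets removed. Of the 30 lists measured in T cells 12 were above the middle 95% of random lists, among them lists of other cell types, milk at 1.40 (0.68 with no UMI minimum), luminal progenitor at 1.02, MHC class II at 0.75 (1.89 with no doublets removed) and lipid-associated macrophage at 0.36.

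Endothelial cells (157 and 110 cells) of the cKO tumor were lower in the cell-cycle list (−1.12, below every random list, 16 of 19 lower and 0 higher, Top2a 9.39-fold lower) and in the endothelial tip cell list (−0.39, below every random list, 10 of 15 lower and 0 higher). The latter marks sprouting vessels, and Cxcr4 and Esm1 (2.32-fold) were among its lower members. Thbs1 was 2.40-fold, Samd4 2.64-fold and Lnx1 4.50-fold lower. The RNA quality list of these cells was lower (−0.16), and the dissociation stress list was higher (0.20). The foreign collagen list stood at 1.69, but at −0.26 among members with at least 100 UMIs and at −0.35 among those above the free RNA guard. The genes named as higher, Ccl21a, Mmrn1, Nts and Neo1, include markers of lymphatic vessels, and lymphatic cells were not split off as a cluster. Mmrn1 was at least 25.9-fold higher, with 111 UMIs in 8 of 157 cells against 0 in 110, and its ratio was 0.755 when no doublets were removed. Ccl21a, which shares its symbol with near-identical copies and is uncertain, was 371-fold higher (103 to 3071) on 4 cells against 1. Its ratio was 1.61 when no doublets were removed and 0.0 when cells were named 1 by 1. Naming 1 by 1 can move cells with lymphatic markers, Mmrn1 among them, to a class of their own, so it does not check these genes.

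The control tumor held more macrophages and luminal cells than the normal gland and fewer lymphocytes and fibroblasts, with age, tissue and depth confounded with the group. Macrophages and monocytes were 27.0% of the tumor's cells and 3.17% (2.64 to 3.78) of the gland's, a ratio of 8.51 (7.08 to 10.2), and luminal cells were 49.1% and 12.9% (ratio 3.82). T cells were 6.07% against 25.7% (ratio 0.236), B cells 0.461% against 19.9% and fibroblasts 6.07% against 30.8% (ratio 0.198). The macrophage ratio ranged from 5.53 at a lower clustering resolution to 15.1 with no doublets removed. Different clusters held most of a class in the 2 tissues: 0, 1, 3 and 4 against 21 for luminal cells, 9 and 5 against 24 and 25 for fibroblasts, 7 against 30 for T cells, and 8, 18 and 14 against 12 and 14 for macrophages. Cluster 30, with Lef1, Tcf7 and Satb1 of the naive T cell list among its leading genes, held 89.8% of gland T cells and 3.80% of tumor T cells. Whether lymphoid tissue came along with the gland was not tested. Glycam1 stood at 135626 CPM in gland endothelial cells (32 cells) and at 0.790 CPM in those of the control tumor. With the B cell share and cluster 30 this leaves the question open. The lymphocyte shares and T cell differences carry that limit. So do the macrophage, luminal and fibroblast shares, because shares of 1 whole move against each other.

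Tumor macrophages had less Cxcr4 than gland macrophages, 13.7-fold (11.7 to 16.2), and also less Retnla (26.6-fold, 26.1 to 27.1), which marks alternative activation, Ear2 (24.9-fold), Aldh1a2 (20.1-fold), Ccl24 (16.5-fold), Cd209f (14.8-fold) and Upb1 (24.6-fold). Retnla, Ear2, Aldh1a2 and Ccl24 are among the leading genes of cluster 12. That cluster held 45.8% of gland macrophages and 3.32% of those of the control tumor. The folds of these genes thus also hold this difference in macrophage clusters. With no doublets removed the ratios of Retnla and Cd209f were 0.0121 and 0.0267, and Upb1 had 0 UMIs in gland macrophages, so its difference ended. The inflammatory cytokine list was higher in the tumor (median log2 ratio 1.73, 16 of 19 members higher and 3 lower), with Il1a 61.8-fold higher (17.1 to 511). The recruitment list was higher too (1.12), with Ccl5 23.3-fold and Ccl12 19.2-fold higher and Ccr2 4.30-fold lower, as was the MHC class II list (0.83, 9 of 13 higher, 2 lower), with Cd86 6.57-fold higher and H2-DMb2 11.0-fold lower. The resident macrophage list was lower (−1.48, 12 of 19 lower, 3 higher), with Ccl24 and Cd209f lower and Stab1 and Ccl8 9.83-fold and 5.07-fold higher. The monocyte list was lower (−0.98, 11 of 16 lower, 2 higher), with Fn1 9.73-fold lower and Cx3cr1 8.93-fold higher. The lipid-associated list (0.28), with Spp1 51.0-fold higher (17.4 to 248) and Lpl 10.8-fold lower, and the CXCL12 axis list (−0.60) lay within 95% of random lists.

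Named as higher in tumor macrophages were Slc8a1 (320-fold, 109.5 to 1553), Immp2l (256-fold, 45.9 to 10107), Arhgap24 (140-fold, 47.8 to 678), Fmnl2, Lrmda, Rnf180, Snx24 and Pde7b (100-fold to 209-fold). At a lower clustering resolution Immp2l was 29.2-fold and Fmnl2 63.2-fold higher, and with no doublets removed the genes other than Immp2l were 46.3-fold to 128-fold higher. Across classes, 13 of the 20 genes named as higher in the tumor had over 100 kb of intron, and 0 of those named as lower. All of those named as higher in macrophages were among the 13. Genes with over 100 kb of intron had median log2 ratios 1.56 to 1.88 above those with at most 1 kb in each of the 4 classes, against gaps of 0.07 to 0.18 between the 2 tumors. By the same rule among genes with at most 5000 bases of intron, chosen after the data were seen, the genes higher in tumor macrophages were Cxcl9 (49.8-fold, 13.7 to 412), Lilra5 (49.4-fold), Zmynd15 (31.3-fold), Ccl12 (19.2-fold, 13.1 to 29.4), Mir142hg (15.9-fold), Ccl4 (9.59-fold), Cd72 (8.83-fold) and Cxcl16 (7.92-fold). At a lower clustering resolution Cxcl9 was 2.89-fold and Ccl4 3.83-fold higher, and with no doublets removed the 8 genes were 3.70-fold to 19.8-fold higher, with Cxcl9 at 19.6-fold.

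**Figure D4:**
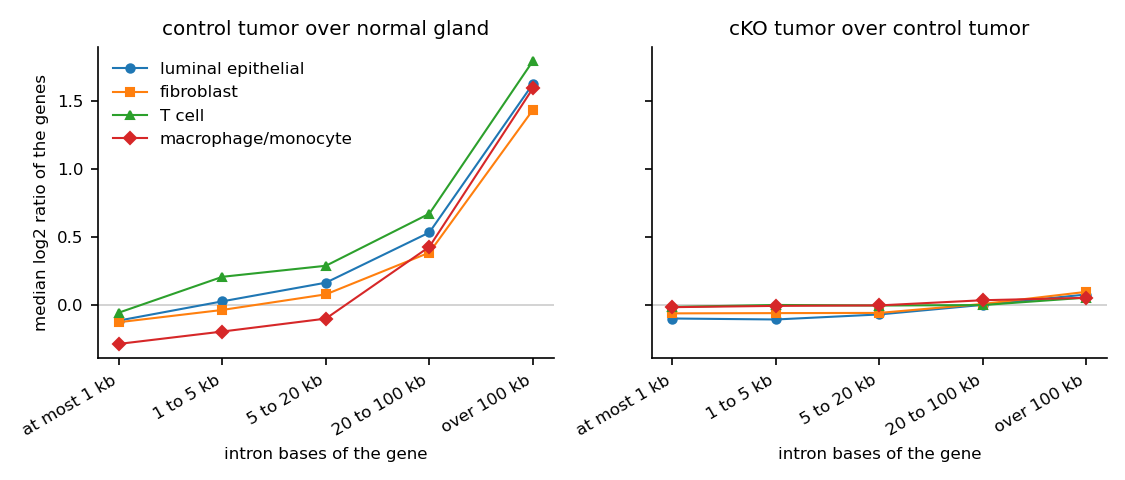
Median log2 ratio of genes with at least 100 UMIs, by the intron bases of the gene, in 4 cell classes, for the control tumor over the normal gland (left) and the cKO over the control tumor (right). On the left the medians are higher for genes with longer introns, with gaps between the end bins of 1.56 to 1.88, and on the right the gaps are 0.07 to 0.18.

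Tumor luminal cells had more milk, progenitor and interferon transcripts than gland luminal cells and fewer hormone-sensing ones. Cluster 21 held 86.8% of gland luminal cells and 0.522% of those of the control tumor. Its leading genes include Prlr, Areg and Cxcl15 of the hormone-sensing list, and Aoc1. The differences below thus also hold this difference in luminal clusters. TMM scaling moved all genes of this class by −0.31, of fibroblasts by −0.39, of T cells by −0.67 and of macrophages by −0.05 on the log2 scale, so lists of luminal cells, fibroblasts and T cells are given as the excess over the median of random lists, while single genes are given by CPM without that shift. That excess was 2.99 for the milk list (12 of 15 members higher, 3 lower), 1.68 for the luminal progenitor list (12 of 16 higher, 2 lower, Csn3 18.1-fold and Wfdc18 13.01-fold higher), 2.31 for the interferon response list (22 of 25 higher, 2 lower, Ifi44 99.2-fold, 48.0 to 247, and Ifit1 35.9-fold) and −3.10 for the hormone-sensing list (12 of 14 lower, 1 higher, Cxcl15 28.9-fold lower). The cell-cycle, stem and hypoxia lists lay within 95% of random lists, with an excess of 0.06, 0.20 and −0.02. Without the correction the cell-cycle median was 0.40, or 2.71 with 2 times the doublet share removed, and the stem median was 0.46, or −0.44 among members with at most 20000 bases of intron. In the stem and hypoxia lists Car9, a hypoxia-induced carbonic anhydrase, was 102-fold higher and Klf4 5.41-fold lower. Scgb1b27 was at least 4613-fold higher, Scgb2b27 3527-fold, Nlrp4e at least 1920.4-fold and Saa2 at least 1895-fold. Gpx3, Defb1 and Aoc1 were 320-fold to 596-fold lower, with Defb1 at a ratio of 0.0017, or 0.0036 with a stricter cell filter.

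Tumor fibroblasts were higher in the myofibroblast list (excess 2.60, 16 of 18 members higher and 0 lower, Col11a1 141-fold and Tnc 70.3-fold), and lower in the interferon (−1.06, 21 of 24 lower, 1 higher) and adventitial lists (−0.95, 11 of 14 lower, 2 higher). Igfbp2 was 933-fold, F5 1356-fold (374 to 11222), Kif26b 463-fold and Chsy3 272-fold higher. Mrgprg was 13.9-fold, Lars2 7.18-fold and Gpx3 6.77-fold lower. Tumor T cells were higher in the exhaustion list (excess 2.98, 11 of 11 members higher, Pdcd1 24.8-fold, 20.5 to 30.2), which holds inhibitory receptors, and in the cytotoxic list (2.54, 15 of 16 higher, 0 lower, Tbx21 49.9-fold), and lower in the naive T cell list (−2.63, 10 of 12 lower, 1 higher, Igfbp4 14.0-fold). Gzmk was 436-fold (119 to 3618), Frmd5 644-fold (177 to 5339), Myo3b 394-fold (69.2 to 15721) and Hip1 125-fold higher. Over the alternatives these folds went down to at least 273 for Gzmk, at least 252 for Frmd5, 248 for Myo3b and 78.5 for Hip1. Of the genes named as higher here, Kif26b, Chsy3, Frmd5, Myo3b and Hip1 have over 100 kb of intron. Their folds may also hold the pattern of long introns given above. Ccr7, which directs naive T cells to lymph nodes, was 13.3-fold, Lars2 21.3-fold and Rflnb 11.2-fold lower. Lars2 was not particular to these classes and stood at 963 to 2877 CPM in the 10 classes of the gland with at least 20 cells. The rule also named Glycam1 as lower in tumor macrophages, fibroblasts and T cells. In the gland it stood at 135626 CPM in endothelial cells (32 cells) and at 36.3 to 84.6 CPM in the 9 other classes, a like low level as free RNA gives, so no difference is read for those classes. The RNA quality list of T cells, which holds mitochondrial and nuclear transcripts, was lower in the tumor (−0.90, 9 of 10 lower). Cxcr4 in T cells was 1.39-fold higher in the tumor by CPM and 0.878 of the gland level under TMM scaling.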

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

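No result met the rules set for a closer look, because groups of 1 library allow no outlier and no difference between groups to be tested. A total of 3 patterns was weighed instead. The tests of immune cells lost alike, of free RNA, of the genotype label and of nuclear RNA were chosen after the result was seen, and the test of intron length after the pattern was seen in other classes.

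The smaller macrophage share of the cKO tumor (ratio 0.589) was set against 3 explanations. Removal of macrophages by the cell filter or with the doublets would bring the ratio near 1 when that step is left out. With either step left out, 1 at a time, it was at most 0.6028. Loss of Lyz2 as a marker would do the same when Lyz2 is left out of the naming, but the ratio stayed at 0.589. A lower share of all immune cells alike would lower T and NK cells as much. Their share ratios were 0.978 (0.824 to 1.16) and 0.949 (0.697 to 1.29), above the interval of the macrophage ratio. Dendritic cells stood at 0.451, and the intervals of neutrophils and B cells were wide. Macrophages per T cell had a ratio of 0.6016 (0.492 to 0.736) in the main naming. For T and NK cells these values argue against the explanation. That ratio was 0.588 to 0.614 in the other settings, but 0.8377 (0.684 to 1.03) with each library clustered on its own. There 139 control macrophages were left unnamed, so the test over all namings cannot tell. The genotype, which includes the near absence of Lyz2 transcripts, may account for the difference, but so may any other difference between 1 tumor and another, and the ratio of shares was 0.778 with each library clustered on its own.

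Cxcr4 UMIs remained in macrophages of the cKO tumor (11.9 CPM). Free RNA of other cells would reach fibroblasts of the same library too, but Cxcr4 stood there at 0.6477 CPM (0.176 to 1.66). T cell RNA in doublets would bring T cell markers along, but the median of 14 markers in these macrophages was 0.4103% of their T cell level (0.190 to 0.689), although the highest reached 37.2%, where Cxcr4 reached 13.1%. A wrong genotype label would leave Lyz2 near its control level, but its ratio was 0.0047. A transcript that keeps its 3′ end after deletion and macrophages that escaped deletion stay open and were not tested.

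Genes with long introns were higher in the control tumor than in the normal gland. The pattern could come from fewer UMIs of introns in the whole normal gland library, for which the gap between long and short introns must also stand in classes outside the 4 where it was found, and it was 1.6164 log2 units in NK cells (1.43 to 1.74) and 1.83 in dendritic cells (1.68 to 1.957, resampling genes). Less nuclear RNA in cells of the normal gland cannot be told apart from this by Malat1 and Neat1, whose median log2 ratio was 0.0596 with values from −0.63 to 0.66 in the 4 classes. The counting of introns in each library is not given in the sources used here, and age and tissue differences were not tested.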

How the results depend on the processing

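Leaving Lyz2 out of the naming, leaving out cluster 18 and limiting introns were tested after the result was seen. No paired analysis was possible because each group is 1 library, and none could be left out. Of 885 recomputed CPM levels 834 stayed within their main interval. So did 273 of 380 shares and 1453 of 1700 ratios, and 2111 of 2183 list medians kept theirs. No value moved out of its interval when Lyz2 was left out. The macrophage share ratio of the tumors ranged from 0.558 to 0.778, its Cxcr4 ratio from 0.752 to 0.960, the luminal cell-cycle list from −0.88 to −0.66 and the interferon lists from −0.31 to −0.20 in macrophages and from 0.49 to 0.62 in luminal cells. The cause was not tested for the changes below, except where given. Depth limits Cxcr4, with 125 UMIs in macrophages of the cKO tumor.

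Without doublet removal, control over normal gave a macrophage share ratio of 15.1, Cxcr4 0.0590 and Cd24a 1.42 in macrophages, the macrophage cell-cycle list 0.65 and fibroblast Cxcl12 1.54. Between the tumors it gave Lyz2 0.0056 in macrophages, with the interferon list at −0.20, cell cycle −0.27 and collagen 1.31. Mesenchymal transition in luminal cells was then −0.061, the hormone-sensing list in fibroblasts −0.079, and in endothelial cells Mmrn1 0.755, MHC class I 0.012 and milk −1.13. With a doubled doublet share the luminal cell-cycle list, control over normal, was 2.71. With no cell filter, doublets still removed, the luminal share ratio, control over normal, was 3.37.

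At resolution 0.5 the macrophage share ratio was 5.53 and macrophage Cxcr4 0.105 for control over normal, and between the tumors the macrophage MHC class II list was −0.076, macrophage cell cycle −0.29 and luminal mesenchymal transition −0.0101. The last was −0.013 at resolution 2.0 too. With each library clustered on its own, the tumors' share ratios were 0.778 for macrophages and 1.26 for luminal cells, the luminal cell-cycle list was −0.87, and in macrophages the resident list was −0.42, inflammatory cytokine −0.51 and dissociation stress 0.0044. Control over normal gave a macrophage share ratio of 6.86 and a fibroblast cell-cycle list of 0.46. Of the share ratio the cause is shown: 139 control macrophages, 134 of them of cluster 18, were left unnamed and 47 were named B cells, while the cKO library gained 39 dendritic and 14 B cells as macrophages. Naming cell by cell gave a luminal share ratio of 3.32 for control over normal. For the tumors it gave a luminal cell-cycle list of −0.88, in T cells Gzma 0.799, Dach2 0.951, the angiogenic list −0.52 and the cytotoxic list −0.13, and in endothelial cells Ccl21a 0.0, with Mmrn1 too low for a value. In that naming Gzma is a marker of NK cells and Mmrn1 of lymphatic cells, so changes of lymphatic genes and Gzma can follow from the naming itself. Without cluster 18 the macrophage share ratio, control over normal, was 7.07, and between the tumors the macrophage inflammatory cytokine list was −0.49 and myofibroblast −0.0026.

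For control over normal, median-of-ratios scaling gave cell cycle 0.0901 and hypoxia −0.12 in luminal cells, fibroblast Cxcl12 1.26 and T cell Cxcr4 0.875. TMM scaling gave 0.0907, −0.12, 1.24 and 0.878, with the fibroblast collagen list at −0.015. These follow from the shifts of all genes. The mean of per-cell CPM gave a luminal cell-cycle list of 0.10, an inflammatory fibroblast list of 0.0702 in T cells, and Lyz2 0.0062 in macrophages of the tumors.

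With no UMI minimum, the tumors' lists were −0.016 for milk in fibroblasts, −0.031 for Wnt in T cells and −0.25 for milk in endothelial cells, and control over normal gave alternative activation 1.06 in fibroblasts and Wnt −1.32 in macrophages. With at least 100 UMIs, the tumors' lists were −0.027 for myofibroblast in macrophages, −0.032 for milk and −0.065 for basal keratin in fibroblasts, −0.031 for stem in T cells and −0.26 for collagen in endothelial cells. Members above the free RNA guard gave −0.35 for the last, and −0.026 for angiogenic factors in fibroblasts, control over normal, which was −0.42 among members with at most 20000 bases of intron. Those members gave, for the tumors, in luminal cells matrix enzyme −0.0002, angiogenic −0.18, mesenchymal transition −0.20 and collagen 1.05, and resident macrophage 0.27 in fibroblasts. The settings of this paragraph change which members enter.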

Other observations

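The list medians below were planned, while the values by cluster, the counts of lymphatic cells, the share of Gm42418 and the short-intron naming were chosen after the result was seen. Cell-cycle transcripts were lower in the cKO tumor in each of the 5 classes compared, with list medians of −0.41 in macrophages, −0.77 in luminal cells, −0.40 in fibroblasts, −0.35 in T cells and −1.12 in endothelial cells. In fibroblasts 9 of 17 members were lower and 0 higher, and the median was −0.087 among the 5 members above the free RNA guard. By the mean of per-cell CPM the median was −0.015 in T cells and −0.61 in endothelial cells. The interferon response list went in opposite directions, lower in macrophages (−0.24), T cells (−0.33) and endothelial cells (−0.15) and higher in luminal cells (0.54), while in fibroblasts it was within 95% of random lists (−0.02, 3 of 24 members higher and 4 lower). In endothelial cells the RNA quality list was lower too. Fibroblasts of the cKO tumor also had lower inflammatory cytokine (−0.45), recruitment (−0.32) and unfolded protein response lists (−0.33).

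Within the monocyte and macrophage clusters, Cxcr4 was lower in the cKO tumor in cluster 14, the cluster with Ly6c2, a marker of recruited monocytes. It stood there at 13.5 CPM (8.00 to 21.3) in the cKO tumor, 30.5 CPM (24.6 to 37.5) in the control tumor and 318 CPM (266 to 378) in the normal gland. In cluster 8, the largest in both tumors, it was 15.5 CPM (12.3 to 19.2) and 13.5 CPM (10.9 to 16.4).

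Lymphatic transcripts in endothelial cells were seen in few cells, with a UMI of Mmrn1 or Prox1 in 15 of 157 endothelial cells of the cKO tumor, 4 of 110 of the control tumor and 7 of 32 of the normal gland. In the normal gland Gm42418, a gene model that overlaps ribosomal RNA, took 3.19% to 8.59% of UMIs in luminal cells, fibroblasts, T cells and macrophages, against 0.405% to 0.762% in both tumors.

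In the short-intron version of the naming rule, added after the data were seen, the genes higher in the tumor than in the normal gland were in fibroblasts Chchd10 (25.2-fold), Mgp (15.7-fold), Mfap4 (10.4-fold) and Ctgf (5.74-fold), and in T cells they included Serpina3g (26.0-fold, 16.4-fold to 49.6-fold over the alternatives), Rgs16 (14.3-fold) and the interferon-induced Ifit3 (13.7-fold). Lower in tumor T cells were S1pr1, a receptor for exit from lymphoid tissue (5.55-fold), Frat2 (6.97-fold) and Zfp281 (5.45-fold). In luminal cells Spp1 was 1782-fold higher (998-fold by the mean of per-cell CPM), and Tmem86a (38.2-fold), Krt6a (20.5-fold), Foxq1 (13.6-fold) and Ly6d (11.8-fold) were lower. Krt6a and Ly6d are among the leading genes of cluster 21, which held most gland luminal cells.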
